A study of Homo sapiens with 2 samples.

How the data were processed

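Single cells of 2 organoid cultures, hSGO and hHFO, were profiled with 1 droplet library each, both from the stem cell line H9 per the labels. Per the labels' protocols, organoids were digested with collagenases and DNase, loaded on the 10x Chromium platform with 3' version 3 chemistry, and sequenced on a NovaSeq instrument. The same protocol text speaks of minced surgical material, which differs from the organoid label, and the label was followed. No culture time, organoid number or count of loaded cells is given in the sources used here. Reads were processed by the authors with Cell Ranger 6.1.2 on build GRCh38, per the file headers and the submitters' processing notes; the annotation release is not given. The deposited values are raw UMI counts per gene and barcode, with no normalization, and every deposited barcode has at least 500 UMIs. The feature list holds 33538 genes in hSGO and 33539 in hHFO, where the added feature Mcherry had 0 UMIs. Of the feature identifiers, 33456 of 33539 were found in GENCODE release 29, which was used for gene positions only. Cell names of the authors were not used here.

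Cells were kept with at least 500 detected genes and at most 20% of UMIs from mitochondrial genes. In hSGO, 562 barcodes had under 500 genes and 396 had over 20% mitochondrial UMIs; in hHFO these were 611 and 839. Doublets were called per library with Scrublet as implemented in scanpy (seed 0) and removed. It marked 2 of 5196 hSGO cells, under the 0.5% below which the caller was taken as not having worked, and 377 of 9808 hHFO cells. Kept cells were 5194 (87.7% of barcodes, 63497652 UMIs, median 3217.5 genes, 4.98% mitochondrial) for hSGO and 9431 (86.6%, 52669921 UMIs, median 1924 genes, 5.62% mitochondrial) for hHFO.

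Each library was clustered alone. Counts were scaled to 10000 per cell and log-transformed, and the 2000 most variable genes, 30 principal components, 15 nearest neighbours and Leiden resolution 0.5 were used. This gave 14 clusters in hSGO and 20 in hHFO. A marker counted as detected where its CPM was at least 2-fold above the median of the library's clusters and at least 10% of the cluster's cells had a UMI. A cluster took the name of the lineage whose marker list had the largest detected share, if that was at least 50% of the list and at least 3 markers. Other clusters stayed unnamed, as did those whose median UMI count, times 3, was under their library's with none of the list's markers among the top 10 genes, and those whose best list was not joined to a class, such as pigment cells. Sympathetic neuron and chromaffin cell lists were joined as sympathoadrenal-like, Schwann cell and neural crest lists as glial or neural crest-like, and endoderm lists as endodermal epithelium-like. The markers in 24 lists, the 24 program lists, the rule for named genes and all alternatives not named here as added were fixed before any deposited value was read. The naming rule, the choice of which clusters to compare and the added alternatives were set after the clusters were seen.

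For each comparison, raw counts of the kept cells were summed per library, class or cluster and scaled to CPM, with an exact Poisson interval for each sum and an exact binomial (Clopper-Pearson) interval for each ratio and share. With 1 library per group there is no test, p-value or standard error, and cells were not treated as replicates. Log2 folds carry a prior of 1 count in each sum. Where a sum was 0, the fold is a lower bound against 3 counts over that sum. A list member counts as measured with at least 50 UMIs in both sums together, and each list is given as its members at least 2-fold higher or lower with the median log2 fold. That median was set beside those of 10000 random lists of the same size matched on expression over 20 bins, as a description of these libraries. Genes were named by a fixed rule: up to 4 members per list with the largest absolute fold, the 10 largest folds in each direction among genes at 100.0 CPM or more, the 5 leading genes of a cluster, and 12 key genes such as TH, SOX10, TNNT2 and ADRB1; other members of the fixed lists are named where they bear on a comparison. Shares of cells with a UMI were computed after thinning each cell to 2000 UMIs. This left out 404 hSGO and 715 hHFO cells below that depth.

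The steps were tested on simulated data drawn as Poisson counts from the pooled gene means and the real depths. These draws hold counting error alone, with no further spread between cells or libraries. They check the computation and cannot show how well the intervals hold on real data. For hSGO against hHFO (17015 genes), 65 of 65 genes simulated at 4-fold had the right direction and 98.5% of intervals held the true fold. There 11 of 16819 unchanged genes passed 2-fold. The share of intervals holding the truth was lowest, at 90.3%, for hHFO cluster 1 against cluster 0 at a simulated 2-fold. For hHFO cluster 14 against clusters 0 and 1 (11484 genes), 648 of 11286 unchanged genes passed 2-fold, so single folds near that size carry little weight there. Of 200 unchanged lists in the whole-library test, 19 fell below the 5th or above the 95th percentile. The highest such count was 28 of 200, for hSGO cluster 13 against cluster 1. Thinned shares of a simulated TH gene were 39.4% and 35.2% at 2 depths, where 37.4% was the truth.

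Alternatives changed 1 choice at a time: gene minimums of 200 and 1000, a 10% or no mitochondrial limit, doublets kept, Leiden resolutions of 0.3 and 1.0, 3000 variable genes, 20 components, and cell cycle genes left out of the variable genes. For levels, they were edgeR TMM factors, median-ratio size factors, totals without mitochondrial and ribosomal protein genes, equal weight per cell, a prior of 5 counts, no UMI minimum, all barcodes, and thinning of both libraries to 2000 UMIs; shares were also computed at 1000 UMIs and with no thinning. Chosen after seeing the data were removal of the 4% of hSGO cells with the highest Scrublet scores, HOX and signalling genes left out of the variable genes, hSGO clusters 5 and 7 left out, and cells under 1000 genes left out of the clusters found at 500. Where an alternative's matched cluster was also part of the pool it was compared with, its folds were taken as void. Under the scalings tried, the median over all genes moved by at most 0.08 log2 in size. Genes that reveal a donor's sex were left out throughout, and results on some other genes of the fixed lists are not given here.

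Software was python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, scikit-learn 1.9.0, python-igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors only.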

Results

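Gene expression was measured in single cells of 2 organoid cultures grown from the human embryonic stem cell line H9. One culture is labelled hSGO and the other hHFO. The series title names organoids of the developing sympathetic ganglion and an exchange between ganglion and heart, and the labels do not spell out either abbreviation. Each group holds 1 library, so no value has a replicate check and no test was possible. Levels are unique molecular identifier (UMI) counts summed over cells and scaled by the total count to CPM. Intervals in brackets are exact 95% Poisson or binomial intervals and cover counting error only. The hSGO library held 5925 barcodes with 64511261 UMIs and a median of 9224 UMIs per barcode. The hHFO library held 10894 barcodes with 57316540 UMIs and a median of 4406 per barcode. After filtering, 5194 hSGO cells remained with a median of 10049.5 UMIs, and 9431 hHFO cells remained with a median of 4612 UMIs. A count of 0 in a whole library allows a level of up to 0.0472 CPM in hSGO and 0.0570 CPM in hHFO.

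The first question was which cell types each organoid held. In hSGO, 2497 of 5194 cells (48.1%, [46.7 to 49.4]) were glial or neural crest-like, in clusters where SOX10 and ERBB3, genes of the Schwann cell lineage, were detected. Sympathoadrenal-like cells made up 29.5% [28.2 to 30.7], with CHGA and CHGB, which code for proteins of hormone-storing granules, detected in 3 of their 4 clusters. Fibroblast-like cells were 2.23% [1.85 to 2.67] of hSGO. In hHFO, 5326 of 9431 cells (56.5%, [55.5 to 57.5]) were cardiomyocyte-like, with TNNT2, the cardiac troponin T gene, in each of their 5 clusters. Fibroblast-like cells were 16.9% [16.1 to 17.6], with 1042 of them in cluster 2. There 9 of 10 listed fibroblast markers were detected, while the top 10 genes held the pericyte marker PDGFRB and none of the listed fibroblast markers. Endodermal epithelium-like cells, with AFP, ALB or FOXA2, were 16.3% [15.6 to 17.1]. Endothelial-like cells with PECAM1 and CDH5 were 1.20%, surface epithelium-like cells with KRT5 and TP63 were 1.02%, and epicardial-like cells with WT1 and TCF21 were 0.498% of hHFO. Unnamed clusters held 20.2% [19.1 to 21.3] of hSGO and 7.61% [7.09 to 8.17] of hHFO cells.

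Class shares rest on markers fixed before the data were examined and on a naming rule set after the clusters were seen. That rule left hSGO clusters 4, 5, 8 and 11 without a name, with 6.97%, 5.99%, 4.77% and 2.48% of the cells. The glial share ran from 34.6% to 54.0% over other processing choices. Over the same choices the unnamed share ran from 12.9% to 33.2% in hSGO, and in hHFO from 6.75% to 12.8%. The doublet caller marked 2 of 5196 hSGO cells (0.0385%), too few for it to have worked. Doublets can therefore remain in that library, and their number was not measured. In hHFO the caller marked 377 of 9808 cells (3.84%), which were removed.

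**Figure D1:**
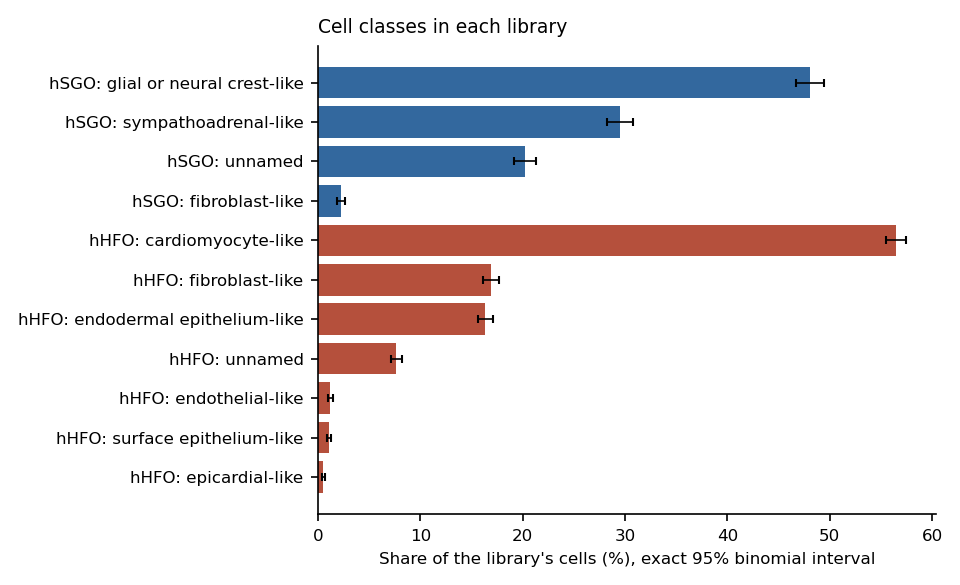
Share of cells, in percent, in each class of the hSGO and hHFO libraries, as bars with exact 95% binomial intervals. The glial or neural crest-like class reached 48.1% of hSGO and the cardiomyocyte-like class 56.5% of hHFO.

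The second comparison set the 2 whole libraries side by side, to ask which programs each organoid expressed. The genes of a sympathetic identity were far higher in hSGO. TH, the rate-limiting enzyme of catecholamine synthesis, stood at 234 CPM against 0.228 CPM (1026-fold, [587 to 1986]). DBH, which converts dopamine to noradrenaline, had 12951 UMIs against 1, a ratio of 10743 [1928 to 424341]. SOX10 was 172-fold [121 to 256] higher in hSGO. These sizes depend on processing. The log2 fold of TH, 9.89, was 9.13 with equal weight per cell. That of DBH, 12.39, was 11.69 with equal weight and 10.81 with a prior count of 5. It was 10.65 with both libraries thinned to 2000 UMIs per cell. With 1 DBH UMI in hHFO, the DBH log2 fold is set largely by the prior and the size of the sums. It therefore lies below the ratio given above. The log2 fold of SOX10, 7.38, was 8.27 after thinning.

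By list, 9 of 10 sympathetic transcription factors were at least 2-fold higher in hSGO (median log2 fold 4.48), with PHOX2A at 328 against 0.456 CPM. Of 11 genes of noradrenaline synthesis and transport, 10 were higher (median 3.51). All 9 neuropeptide genes were higher (median 4.42), led by VIP with 391 CPM from 24799 UMIs against 2 in hHFO, and by GAL with 1139 against 5.30 CPM. Of the cholinergic genes, 3 were measured and all were higher (median 7.58), with the choline transporter gene SLC5A7 at 16.6 against 0.0380 CPM. CHAT, which makes acetylcholine, was near the detection limit in both libraries, with 6 UMIs in hSGO and 0 in hHFO. All 5 measured nicotinic receptor genes (median 5.12; CHRNA3 296 against 6.76 CPM), all 10 synaptic vesicle genes (median 3.46) and 8 of 11 neuronal ion channel genes (median 2.76) were higher. Each of these medians lay above those of at least 9998 of 10000 random lists matched on expression.

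HOX genes, which record position along the body axis, were also higher in hSGO: 13 of 13 measured genes of groups 1 to 5 (median log2 fold 5.47) and 10 of 11 of groups 6 to 9 (median 4.27). HOXB5 stood at 59.9 against 1.33 CPM and HOXC9 at 4.09 against 0.133 CPM. Of groups 10 to 13, 0 of 12 genes reached 50 UMIs. With both libraries thinned to 2000 UMIs per cell, 5 genes of groups 6 to 9 were counted as higher in place of 10. Thinning lowers the sums while the minimum of 50 UMIs stays, so genes can leave the count without a smaller fold. How many were still measured is not given here.

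The heart program had the opposite direction. All 15 sarcomere genes were lower in hSGO (median log2 fold -11.79): MYL2, a ventricular myosin light chain gene, had 0 against 79927 UMIs (at least 32119-fold lower), and TNNT2 was 8992-fold [5758 to 14936] lower. All 8 calcium-handling genes (median -7.24; RYR2 2.39 against 323 CPM), all 7 ventricular genes (median -7.73) and 8 of 9 atrial genes (median -6.88, or -5.85 with bounds in place of zero counts) were lower. GATA4 and NKX2-5, cardiac transcription factors, had 0 UMIs in hSGO against 3677 and 2614. Of the 10 genes on that list, 6 were lower and 2 higher (median -4.28). Collagens and matrix genes were lower for 10 of 12 (median -4.69; COL1A1 97.4-fold, a log2 fold of -6.60 that was -5.99 after thinning). Pacemaker genes split, with 5 of 9 higher and 2 lower in hSGO: SHOX2, also a neuronal gene, was 17.4-fold higher and TBX18 231-fold lower. SPINK1, an epithelial secreted inhibitor, had 0 UMIs against 95296 (at least 38296-fold lower), and AFP, a fetal liver gene, had 1 UMI against 31997.

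Genes of signalling between nerve and target also differed between the libraries. Of 8 neurotrophic factor receptor genes, 6 were higher in hSGO (median log2 fold 2.45), including RET at 101 against 0.608 CPM, whose log2 fold of 7.34 was 6.36 with equal weight per cell and 6.58 after thinning. NTRK2 was 14.2-fold lower. Of 10 ligand genes, 3 were higher, with GDNF at 34.9 against 0.380 CPM, and 6 were lower (median -1.85), with EDN1 at 0.425 against 25.5 CPM. That count of 6 was 3 after thinning to 2000 UMIs per cell, where genes that fall under the UMI minimum also leave the count. Of 6 adrenergic and muscarinic receptor genes, 4 were lower (median -1.62), with CHRM2, the muscarinic receptor of heart muscle, at 2.35 against 34.3 CPM. Cell cycle genes were higher for 4 of 12 (median 0.65), Notch pathway genes split 4 against 4 (median 0.77), and stress (median -0.14) and hypoxia genes (median 0.05) were close to balance. The median over all 17021 measured genes was 0.07. These whole-library folds do not separate the mix of cell types in each culture from levels within 1 type.

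**Figure D2:**
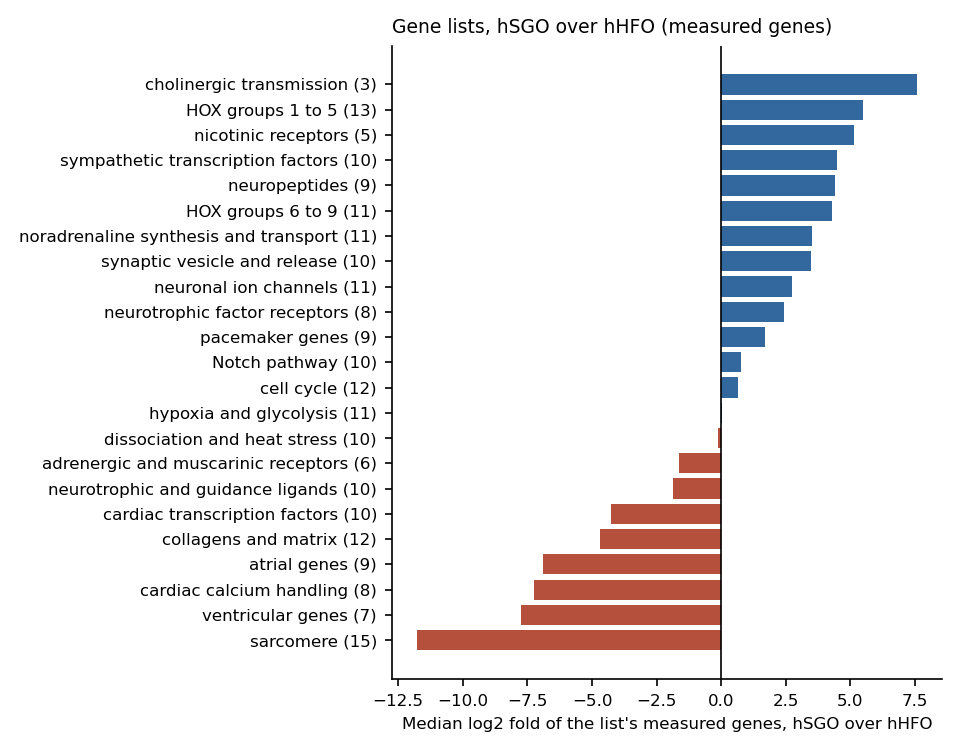
Median log2 fold, hSGO over hHFO, of each fixed gene list, with the number of measured genes in brackets. Cholinergic genes had the highest median (7.58) and sarcomere genes the lowest (-11.79).

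Within hSGO, the most frequent sympathoadrenal-like cluster (cluster 1, 1049 cells) was set against the most frequent glial cluster (cluster 0, 1263 cells), to describe the noradrenergic cells. All 11 genes of noradrenaline synthesis and transport were at least 2-fold higher in cluster 1 (median log2 fold 5.87). TH stood at 616 against 10.6 CPM (58.3-fold, [48.7 to 70.5]), DBH at 526 against 8.50 CPM, and the noradrenaline transporter gene SLC6A2 at 105 against 0.716 CPM. PNMT, which makes adrenaline, was 43.8-fold [25.5 to 82.5] higher at 50.9 CPM. Of 8 chromaffin cell markers, 7 were detected in cluster 1, and of 13 sympathetic neuron markers, 10, so the name covers both. SOX10 was 23.5-fold lower.

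Sympathetic transcription factors split between these clusters: 6 of 10 were higher, led by GATA3 (160-fold) and TFAP2B (139-fold), and 2 were lower. NPY, a co-transmitter of sympathetic neurons, was 136-fold higher, and SHOX2 was 174-fold higher. All 10 synaptic vesicle genes (median log2 fold 4.16), 9 of 10 ion channel genes (median 3.02), all 5 nicotinic receptor genes (median 1.89) and all 3 measured cholinergic genes (median 4.48) were higher. Neuropeptide genes were higher for 6 of 9 and lower for 1. Hypoxia and glycolysis genes were higher for 7 of 10 (median 2.11), with LDHA at 1235 against 83.9 CPM. Dissociation and heat stress genes were lower for 4 of 10 and higher for 1 (median -0.81), with FOS 5.68-fold lower. Notch pathway genes were lower for 5 of 8 (median -2.78), with HES1, a Notch target, 30.1-fold lower. Matrix genes were lower for 6 of 7 (median -3.40). Lineage genes also drew and named these clusters, so the folds describe the clusters and do not test them. The SOX10 log2 fold of -4.55 was -6.32 with the 4% of cells of highest doublet score removed, an alternative chosen after seeing the data, and -5.78 at a minimum of 1000 genes per cell.

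HOX genes differed by group between the noradrenergic and glial clusters. Of 13 genes of groups 1 to 5, 8 were lower in cluster 1 and 2 were higher (median log2 fold -1.63), with HOXB4 at 2.77 against 85.4 CPM and HOXB5 at 7.78 against 47.9 CPM. Of 8 genes of groups 6 to 9, 4 were lower and 3 higher (median -0.40), with HOXD9 at 14.6 against 0.716 CPM and HOXD8 at 37.8 against 6.17 CPM.

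A separate question was whether hSGO neurons were all of 1 kind. Cluster 11 (129 cells, median 18564 UMIs) expressed VIP, a peptide of cholinergic autonomic neurons, at 3492 CPM against 19.6 CPM in cluster 1 (178-fold, [161 to 199]). That log2 fold of 7.48 was 8.81 with the 4% of cells of highest doublet score removed, an alternative chosen after seeing the data, and 8.03 at a minimum of 1000 genes per cell. In it, 10 of 11 noradrenaline genes were lower (median log2 fold -4.89): DBH stood at 4.96 against 526 CPM, TH at 31.3 against 616 CPM, and the vesicular transporter gene SLC18A1 had 0 UMIs (at least 106-fold lower). Of 3 measured cholinergic genes, 2 were higher, with SLC5A7 at 75.6 against 4.58 CPM. Of synaptic vesicle genes, 0 of 10 differed 2-fold, and of nicotinic receptor genes 0 of 5. Hypoxia and glycolysis genes were lower for 3 of 10 (median -0.52), and the 10 dissociation and heat stress genes had a median of -0.46 with 0 past 2-fold. Of 10000 random lists, 4 and 8 had a median as low. Neuropeptide genes were higher for 4 of 9 and lower for 3. Sympathetic transcription factors were lower for 5 of 10 and higher for 2 (median -1.45), with GATA2 at 3 against 3547 UMIs, a ratio of 165 [56.5 to 801]. RET was 2.70-fold higher.

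HOX genes of groups 1 to 5 set cluster 11 apart from cluster 1. Of 12 measured, 8 were higher and 0 lower (median log2 fold 2.42), with HOXB5 at 453 against 7.78 CPM (58.2-fold, [49.0 to 69.7]) and HOXA5 at 235 against 2.99 CPM (78.6-fold). Groups 6 to 9 split 4 against 4, with HOXD8 at 7.25 against 37.8 CPM. CHRM2 was also higher in cluster 11, at 22.1 against 0.267 CPM. Leaving HOX and signalling genes out of the clustering gave a matched cluster of 131 cells, 129 of them from cluster 11.

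Cluster 13 (94 cells, median 29889 UMIs) held neurons with another set of transmitter genes. All 3 measured cholinergic genes were higher than in cluster 1 (median log2 fold 2.42), with SLC5A7 at 241 against 4.58 CPM (52.6-fold, [42.0 to 66.6]) and the vesicular acetylcholine transporter gene SLC18A3 at 79.8 against 14.9 CPM. Of 11 noradrenaline genes, 10 were lower (median -2.81), with TH at 80.2 CPM and DBH at 17.0 CPM. The peptide genes TAC1 (73.3-fold), SST (31.9-fold) and PENK (20.3-fold) were higher, as were RELN (63.4-fold) and UTS2 (33.0-fold). HOX groups 1 to 5 were higher for 6 of 11 genes (median 1.11) and groups 6 to 9 lower for 3 of 6. Dissociation and heat stress genes were lower for 3 of 10 and higher for 1 (median -0.60). CHAT had a level of 0.706 CPM in cluster 13, 0.763 CPM in cluster 11 and 0.107 CPM in cluster 1, so a cholinergic phenotype was not detectable from that gene at this depth. Cluster 13 had about 2 times the UMIs per cell of cluster 1, and the doublet caller marked too few hSGO cells to rule out doublets.

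**Figure D3:**
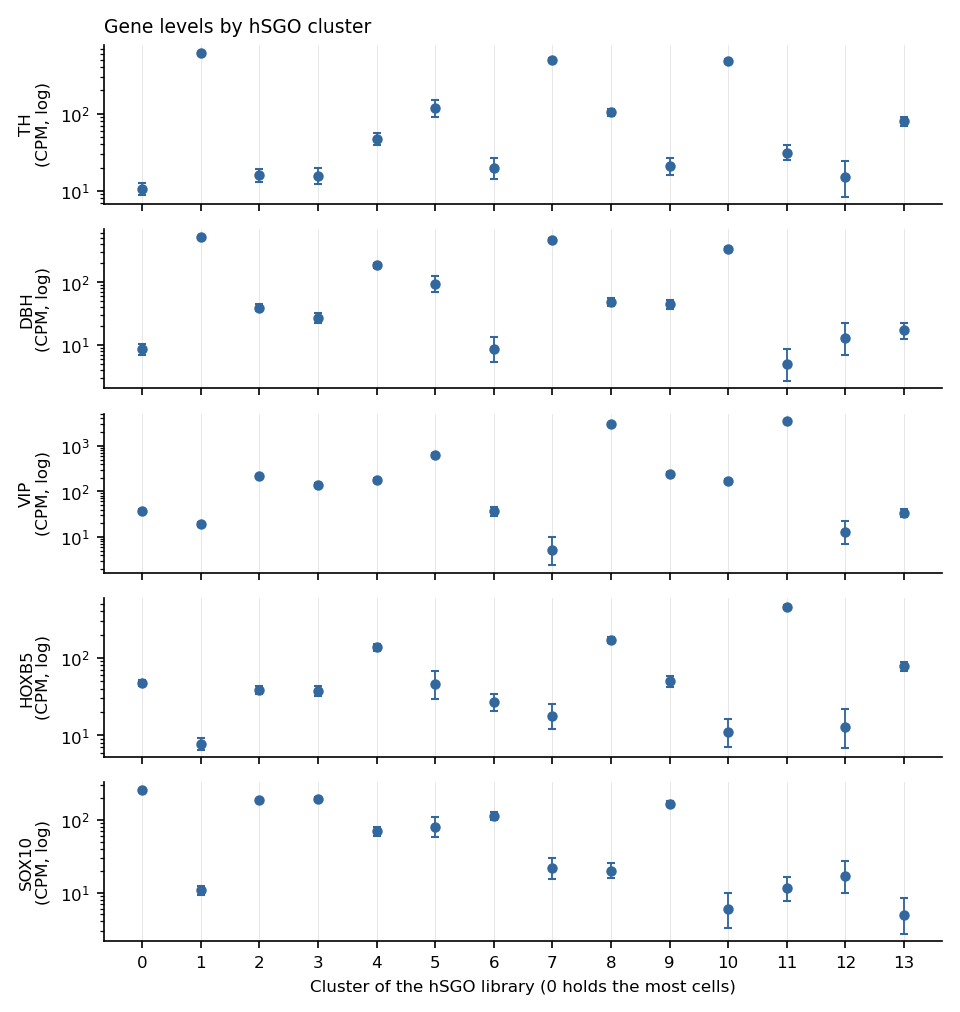
Levels of TH, DBH, VIP, HOXB5 and SOX10 in CPM on a log axis in each hSGO cluster, with exact 95% Poisson intervals. TH reached 616 CPM in cluster 1, and VIP and HOXB5 reached 3492 and 453 CPM in cluster 11.

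Within hHFO, the cardiomyocyte-like clusters were compared with each other to describe the kinds of heart muscle cell present. Cluster 14 (108 cells) had higher levels of pacemaker genes than clusters 0 and 1 together. SHOX2, a transcription factor of the sinus node, stood at 201 against 0.598 CPM (336-fold, [186 to 666]), TBX3 at 191 against 12.2 CPM (15.7-fold) and VSNL1 at 259 against 6.37 CPM (40.7-fold). HCN4, the pacemaker channel gene, was 2.60-fold [1.99 to 3.36] higher. In all, 8 of 9 pacemaker genes were higher (median log2 fold 3.70), as were 8 of 8 measured atrial genes (median 2.97; NPPA 10.7-fold, NR2F2 26.5-fold). Of 7 ventricular genes, 6 were lower (median -2.30; MYL2 214 against 3038 CPM). NKX2-5, low in the sinus node head, was 2.76-fold lower, and TNNT2 was within 2-fold (4924 against 5325 CPM).

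Matrix genes (7 of 11 higher, 1 lower, median 1.74) were also higher in cluster 14, as were the smooth muscle genes MYLK (192-fold) and MYH11 (173-fold). Beside 12 of 13 cardiomyocyte markers, 6 of 10 fibroblast and 6 of 8 smooth muscle or pericyte markers were detected in cluster 14. Of the latter list, 3 were detected in cluster 0 and 5 in cluster 1. Other cells or doublets mixed into cluster 14 were not tested. Cell cycle genes were higher for 6 of 11 (median 1.01). The prior of 1 count weighs more on the sum of cluster 14 (648257 UMIs) than on the pool (20079430 UMIs). It lifts folds of genes with few counts, and the random lists had a median of 0.17. The cell cycle list summed to 430 CPM in cluster 14 against 313 and 298 CPM in clusters 0 and 1. After thinning, 3.88% [1.07 to 9.65] of cluster 14 cells had a MKI67 or TOP2A UMI, against 2.31% and 1.12%. Cardiomyocyte-like cluster 3, at 56.9%, is left out of this pair. MYH6 stood at 3594 against 297 CPM and MYH7 at 467 against 4024 CPM; these neighbouring myosin genes are near-identical in part, and how shared reads were counted is not given in the sources used here. Cluster 14 depended on the clustering: at a minimum of 1000 genes per cell its cells fell mostly into a cluster of 789 cells, and at Leiden resolution 1.0 into one of 465 cells, both part of the matches of clusters 0 and 1. The clusters were also kept with cells under 1000 genes left out, a choice made after seeing the data. Then 8 pacemaker genes were higher and the HCN4 log2 fold was 1.41. That choice kept 105 of the 108 cluster 14 cells, so these values could hardly change. It does not test the dependence on clustering.

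Cluster 10 (241 cells) had a partly atrial pattern against clusters 0 and 1. NPPA, the atrial natriuretic peptide gene, was 14.6-fold [13.8 to 15.3] higher at 2214 CPM, MYL7 was 2.37-fold higher, and 5 of 7 measured atrial genes were higher (median log2 fold 1.24). Ventricular genes were lower for 3 of 7 and higher for 1 (median -0.995), and cardiac transcription factors were lower for 6 of 10 (median -1.22). The largest folds were of EPHA4 (105-fold), MYL1 (105-fold) and NEB (79.3-fold), the last 2 being genes of muscle fibres. MYL1 came from few cells, as 3.32% of cluster 10 had a UMI of it, against 83.0% for EPHA4 and 34.0% for NEB. SHOX2 was near its limit of detection, with 2 UMIs in cluster 10. At a minimum of 1000 genes per cell, and at Leiden resolution 1.0, 2 atrial and 1 ventricular gene passed 2-fold in the direction given, and the NPPA log2 fold of 3.86 was 3.03 and 3.12. Between clusters 1 and 0, NPPB (32.1-fold), ACTA1 (16.2-fold), NPPA (11.9-fold) and ANKRD1 (11.7-fold) were higher in cluster 1, while TNNT2 and NKX2-5 were within 2-fold. NPPB had a UMI in 14.4% and ACTA1 in 9.19% of cluster 1 cells, so a part of the cluster carried these levels. The NPPB log2 fold of 4.98 was 5.66 with HOX and signalling genes left out of the clustering, a choice made after seeing the data.

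Fibroblast-like cells were found in both libraries and are compared by cluster number, because pericyte markers were detected beside the fibroblast markers. In hHFO cluster 2, 9 of 10 listed fibroblast markers were detected, but its top genes held PDGFRB, a pericyte marker, and none of these. Of 8 smooth muscle or pericyte markers, 5 were detected in hHFO cluster 2 and 6 in hSGO cluster 12. hSGO cluster 12 (116 cells) had lower matrix gene levels than hHFO cluster 2 (1042 cells) and cluster 5 (434 cells). Against cluster 2, 9 of 12 matrix genes were lower (median log2 fold -1.81), with COL1A1, a chain of type I collagen, at 935 against 13699 CPM. Against cluster 5, 11 of 12 were lower (median -2.56). Cell cycle genes were higher in hSGO cluster 12, for 9 of 12 genes against cluster 2 (median 1.61) and 8 of 10 against cluster 5 (median 1.85), but the cycling hHFO fibroblast-like cells form cluster 12 of hHFO, which these pairs leave out. Over the whole class the cell cycle list summed to 1290.28 CPM in hSGO and 1400.15 CPM in hHFO. Dissociation and heat stress genes were also higher in hSGO cluster 12, for 3 of 10 against cluster 2 (median 0.73) and 5 of 10 against cluster 5 (median 0.90), with JUN 3.57-fold and 5.61-fold higher. TNNT2 stood at 660 CPM in hHFO cluster 2 and 4.98 CPM in hSGO cluster 12, so heart muscle transcripts were present on the hHFO side. Library and class cannot be separated with 1 library each.

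The series title names a crosstalk of ganglion and heart, so the receptor and ligand genes were followed by class. CHRM2, through which acetylcholine slows the heart, was found in 9.42% [8.62 to 10.3] of cardiomyocyte-like cells thinned to 2000 UMIs (median depth 4368.5 before thinning, 19.9% unthinned). In endodermal cells, which should lack it, the share was 0.811% [0.420 to 1.41], at a median depth of 6262. It was 33.0% [24.1 to 43.0] in cluster 14, against 9.47% in clusters 0 and 1, and 14.4% [10.9 to 18.5] in fibroblast-like cluster 5. By level, CHRM2 reached 199 CPM in cluster 14 and 55.0 CPM in clusters 0 and 1 (3.62-fold, [2.99 to 4.35]). In cluster 10 CHRM2 was 3.32-fold [2.18 to 5.32] lower than in clusters 0 and 1, at 16.5 CPM.

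ADRB1, the main beta receptor of adult heart muscle, had a UMI in 6 of 4979 cardiomyocyte-like cells (0.121%, [0.0442 to 0.262]), against 1 of 1480 endodermal cells (0.0676%). These counts are too small to tell whether its share was above background at this depth. ADRB1 stood at 10.8 CPM in cluster 14 from 7 UMIs. That level rests on few UMIs and is not set against other clusters here.

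On the nerve side, TH was found in 57.9% [55.3 to 60.5] of sympathoadrenal-like cells (86.2% unthinned, median depth 14362) and in 1.86% [1.36 to 2.47] of glial cells (median depth 9929). RET was found in 55.1% [48.7 to 61.5] of cluster 8, 27.9% [20.4 to 36.5] of cluster 11 and 2.72% [1.89 to 3.78] of cluster 0. NRG1, a ligand for heart and glial ERBB receptors, was found in 12.2% [10.55 to 14.02] of sympathoadrenal-like cells against 0.282% of glial cells. Glial cells in turn held GDNF, the ligand of the RET complex, in 13.9% [12.6 to 15.3] against 1.05% of sympathoadrenal-like cells.

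SEMA3A, which repels sympathetic axons, was found in 10.3% [9.51 to 11.2] of cardiomyocyte-like cells against 2.91% [2.11 to 3.89] of endodermal cells. Its level was 197 CPM in cluster 10 against 48.4 CPM in clusters 0 and 1 (4.07-fold, [3.54 to 4.67]). In cluster 14 the SEMA3A fold was 2.23. EDN3 and EDN1, endothelin genes, were highest in endodermal cluster 9, at 293 and 201 CPM. Thinning left out 404 hSGO and 715 hHFO cells under 2000 UMIs. Heart muscle transcripts were spread over other cells of hHFO, where TNNT2 was found in 33.2% [30.8 to 35.6] of endodermal cells, 35.5% [33.0 to 38.0] of fibroblast-like cells, against 98.5% [98.1 to 98.8] of cardiomyocyte-like cells.

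**Figure D4:**
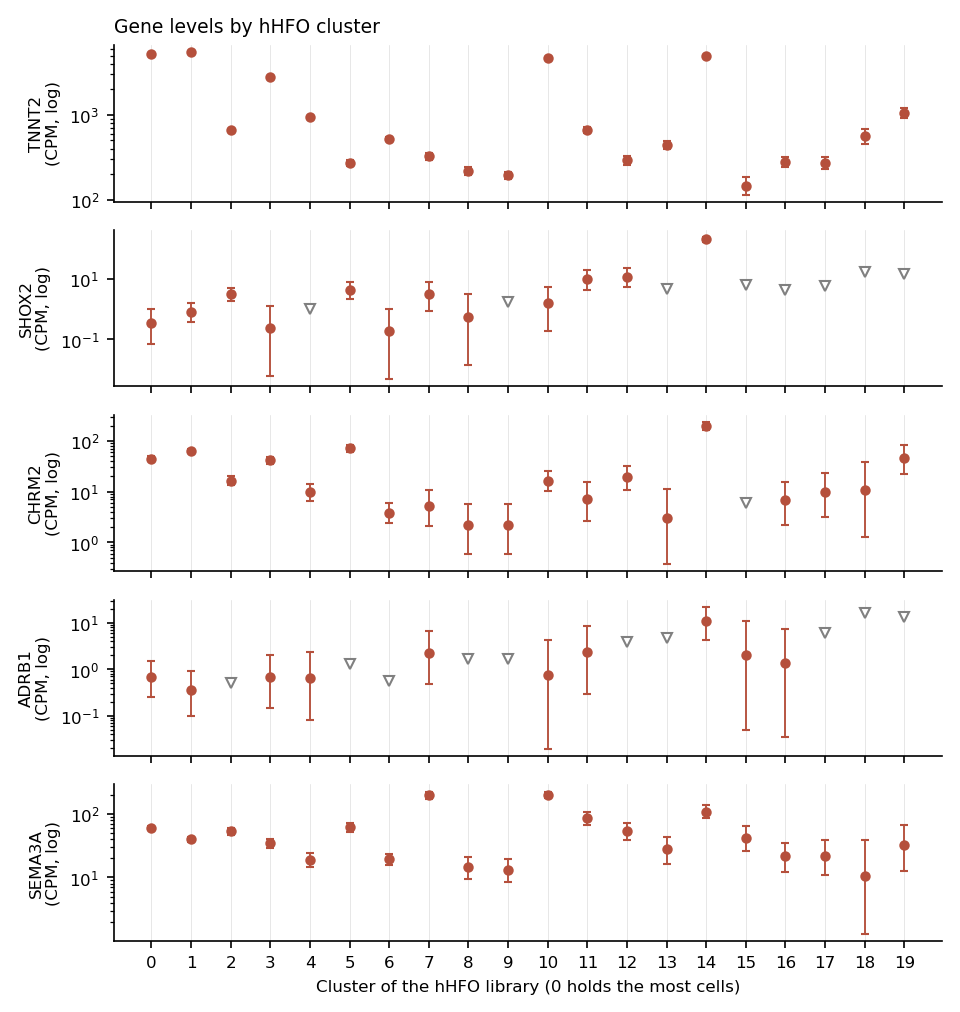
Levels of TNNT2, SHOX2, CHRM2, ADRB1 and SEMA3A in CPM on a log axis in each hHFO cluster, with exact 95% Poisson intervals; open triangles mark the limit that 0 UMIs allows. SHOX2 and CHRM2 were highest in cluster 14, at 201 and 199 CPM.

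Dividing cells were counted as those with a UMI of MKI67 or TOP2A, genes expressed in cycling cells, after thinning to 2000 UMIs. Glial or neural crest-like cells had the highest share among named classes, 742 of 2478 (29.9%, [28.1 to 31.8]; 41.4% unthinned), with clusters 2 and 9 at 95.7% and 97.5%. Sympathoadrenal-like cells stood at 11.4% [9.83 to 13.2], with most of the dividing cells in cluster 10 (83.1%, [75.5 to 89.1]) and 4.05% in cluster 1. The neurons of clusters 11 and 13 stood at 2.33% [0.482 to 6.65] and 2.13% [0.259 to 7.48]. In hHFO, cardiomyocyte-like cells stood at 7.91% [7.18 to 8.70], with cluster 3 at 56.9%. Fibroblast-like cells stood at 12.4% [10.7 to 14.2] in hHFO and 15.2% [8.97 to 23.6] in hSGO, and endodermal cells at 5.34% [4.25 to 6.61]. In epicardial-like cells, 0 of 45 had such a UMI, which allows up to 7.87% of cells with a UMI at that depth. That bound does not limit cells that express these genes (6.38% unthinned). Unnamed clusters stood at 5.37% in hSGO (19.5% unthinned) and 20.5% in hHFO, where cluster 7 reached 37.9%. hSGO cluster 5 stood at 38.2% from 21 of 55 cells, with 256 of its cells too shallow to count. Free RNA can add to such shares. Cycling genes were among the top genes of clusters 2, 3, 5, 9 and 10 of hSGO and 3 and 12 of hHFO. They can have helped draw these clusters, whose shares are then no separate evidence.

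**Figure D5:**
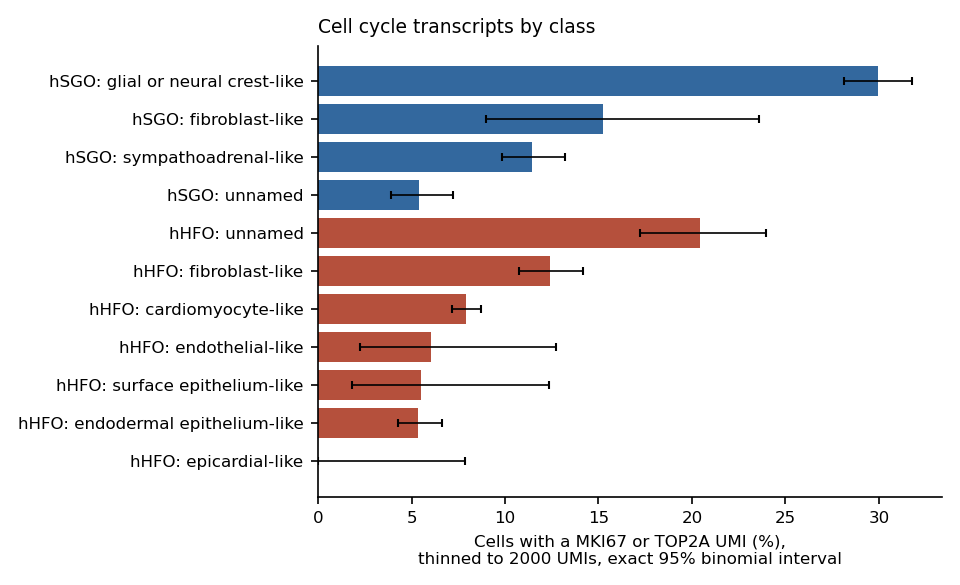
Share of cells, in percent, with a MKI67 or TOP2A UMI after thinning to 2000 UMIs in each class, as bars with exact 95% binomial intervals. The glial or neural crest-like class stood at 29.9% and the cardiomyocyte-like class at 7.91%.

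The positions of the genes on which the comparisons rest come from GENCODE release 29 on build GRCh38, where all are protein coding genes. TH (ENSG00000180176) lies on chromosome 11 from 2163929 to 2171877 and DBH (ENSG00000123454) on chromosome 9 from 133635348 to 133659344. VIP (ENSG00000146469) lies on chromosome 6 from 152750798 to 152759765, and HOXB5 (ENSG00000120075) on chromosome 17 from 48591257 to 48593961. SOX10 (ENSG00000100146) lies on chromosome 22 from 37970686 to 37987422. SHOX2 (ENSG00000168779) lies on chromosome 3 from 158095954 to 158106503, CHRM2 (ENSG00000181072) on chromosome 7 from 136868669 to 137020255, and TNNT2 (ENSG00000118194) on chromosome 1 from 201359008 to 201377762. ADRB1 (ENSG00000043591) lies on chromosome 10 from 114044056 to 114046908.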

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

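Removing the 4% of hSGO cells with the highest Scrublet scores, leaving out HOX and signalling genes from the variable genes, leaving out hSGO clusters 5 and 7, and leaving out cells under 1000 genes from the clusters found at 500 were tests chosen after the results were seen. No paired analysis was possible because each group holds 1 library. Of 206 alternative values for counts of list members in the main results, 196 stayed within 1.5 times, and 42 of 64 log2 folds and 36 of 97 shares stayed within the counting interval of the value given in the results. Among other values, 197 log2 folds and 21 shares stayed within it, 52 and 16 moved, and 1 changed sign. These tallies include the values of cluster 14 taken as void, the 1 change of sign among them. Alternatives were run for some of the list counts only, and the 10 that moved are those of clusters 14 and 10 and of thinning given here. The cause of these moves was not tested. Depth limits genes near the floor, such as CHAT and ADRB1, and clusters of about 100 cells.

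At a minimum of 1000 genes per cell, 78.5% of hSGO and 80.2% of hHFO barcodes were kept, the glial share was 53.7%, the cardiomyocyte share 57.6% and the endodermal share 17.3%. The cluster 1 log2 fold of SOX10 was -5.78, that of HOXB5 in cluster 11 was 6.21, and those of COL1A1 in hSGO cluster 12 were -3.69 and -3.78 against hHFO clusters 2 and 5, where the match of cluster 5 (185 cells) held 137 of its 434 cells and so is a poor check. The match of hHFO cluster 14 was a cluster of 789 cells that also lies in the match of clusters 0 and 1, so it was set against a pool that holds it, and its folds do not bear on cluster 14. It had 5 pacemaker and 4 atrial genes higher and 1 ventricular gene lower, with log2 folds of 0.0224 for HCN4, 0.74 for CHRM2 and -0.0760 for SEMA3A, the last with its sign reversed. The match of cluster 10 had 2 atrial genes higher and 1 ventricular gene lower, with 3.03 for NPPA and 1.79 for SEMA3A, and NPPB in the match of cluster 1 was 4.38. That match is the same cluster of 789 cells and holds 665 of 2166 cluster 1 cells, so the value does not bear on cluster 1. With the clusters kept and cells under 1000 genes left out, 105 of 108 cluster 14 cells remained, so little could change. Cluster 14 then had 8 pacemaker and 8 atrial genes higher and 6 ventricular genes lower. Its log2 folds were 1.41 for HCN4, 1.87 for CHRM2 and 1.21 for SEMA3A. This does not test the dependence on clustering. At a minimum of 200 genes, 93.3% and 92.3% of barcodes were kept, and the shares were 34.6% glial, 50.7% cardiomyocyte, 17.7% hHFO fibroblast and 17.2% endodermal.

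With a 10% mitochondrial limit, 84.8% of hSGO and 76.4% of hHFO barcodes were kept and the cardiomyocyte share was 54.4%. With no limit, 90.5% and 89.9% were kept, with 36.98% glial, 27.6% sympathoadrenal, 53.3% cardiomyocyte, 16.1% hHFO fibroblast and 15.3% endodermal cells. With called doublets kept, hHFO kept 90.03% of barcodes, with 54.4% cardiomyocyte and 17.3% endodermal cells, and COL1A1 against cluster 2 was -3.76. With the 4% of hSGO cells of highest Scrublet score removed, 84.2% of barcodes were kept and 46.1% of cells were glial, with log2 folds of 6.19 for TH, -6.32 for SOX10 and 6.35 for HOXB5.

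At Leiden resolution 1.0, shares were 42.8% glial, 58.2% cardiomyocyte and 14.9% endodermal. The match of cluster 14 (465 cells), again part of the pool it was set against, had 1 ventricular gene lower, with 0.11 for HCN4 and 0.97 for CHRM2. The match of cluster 10 had 2 atrial genes higher, 1 ventricular gene lower and 3.12 for NPPA. At resolution 0.3 the sympathoadrenal share was 36.7%. With 3000 variable genes the glial share was 40.7% and the cardiomyocyte share 53.96%, and with 20 components the glial share was 40.1%. Without cell cycle genes, shares were 45.5% glial, 53.8% cardiomyocyte and 17.4% endodermal. Without hSGO clusters 5 and 7, shares were 53.99% glial and 27.5% sympathoadrenal. With HOX and signalling genes left out of the variable genes, NPPB in hHFO cluster 1 was 5.66.

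With equal weight per cell, log2 folds were 6.38 for HOXB5 in cluster 11, 6.28 for SLC5A7 in cluster 13, 4.23 for NPPA in cluster 10, 4.63 for NPPB and -3.86 for COL1A1 against cluster 5. With both libraries thinned to 2000 UMIs per cell, 5 genes of HOX groups 6 to 9 were higher and 3 ligand genes lower. These counts leave out genes that fall under the UMI minimum after thinning, so they do not show that folds shrank. At a thinning depth of 1000 UMIs, TH was found in 45.4% of cluster 1 and 0.794% of cluster 0, and CHRM2 in 16.7% of cluster 14, 4.98% of clusters 0 and 1 and 6.84% of cluster 5. Cycling shares were then 23.9% glial, 7.70% sympathoadrenal, 8.85% hSGO fibroblast, 5.87% cardiomyocyte, 9.36% hHFO fibroblast and 3.21% endodermal. With no thinning, TH was found in 94.7% and 7.76%, RET in 73.6% of cluster 11, and CHRM2 in 60.2%, 19.2% and 23.7%. Cycling shares were then 41.4%, 22.2%, 26.7%, 12.04%, 16.3% and 11.2% in the same order.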

Other observations

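All tests of the HOX pattern and 2 of the 3 tests of heart muscle transcripts were chosen after the result was seen. Several hSGO clusters carried programs that no comparison covered. In glial cluster 6 (272 cells), GDF15, a stress gene, PTGDS and APOE led: GDF15 stood at 139 CPM, PTGDS at 132 CPM and APOE at 1220.03 CPM, against 2.77, 8.86 and 296 CPM in cluster 0. GDNF stood at 165 CPM there and 78.7 CPM in cluster 0. The top genes of cluster 6 also held P4HA1 of the hypoxia list and ATF3 of the stress list. Its median mitochondrial share was 2.36%, against 5.32% in cluster 0. Cluster 7 (258 cells, median 2829 UMIs), sympathoadrenal-like by its markers, was led by the hypoxia genes ADM (100.4 CPM) and ANKRD37, with VEGFA at 392 CPM and SST at 2381.4 CPM. Cluster 4 (362 cells) joined DBH at 187 CPM with the progenitor gene DLL3 (379.7 CPM) and with TLX3 at 116 CPM. Cluster 8 (248 cells) held VIP at 2971 CPM, GAL at 6853 CPM, RET at 413 CPM and the Notch ligand DLL3 at 416 CPM. Cluster 5 (311 cells, median 1204 UMIs, 0.838% mitochondrial UMIs) had 5875 CPM of MALAT1, a nuclear RNA, against 27228 CPM in cluster 0. Its leading gene TTR, at 513 CPM, came from 0.322% of its cells and so does not describe the cluster.

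Cells outside the heart lineages made up other clusters of hHFO. Cluster 7 (362 cells) expressed the retinal progenitor genes RAX (134 CPM) and PAX6 (530.3 CPM). Cluster 15 (104 cells) expressed 6 of 6 pigment cell markers, with PMEL at 3480.35 CPM and TYR at 278 CPM. Cluster 11 (223 cells) expressed the neuronal genes ELAVL4 (261 CPM) and POU4F2 (249 CPM). CGA and INS, hormone genes with high sums in cluster 11, each had a UMI in 1.345% of its cells, so few cells carried them. Among endodermal clusters, cluster 8 (339 cells) held the pancreatic enzyme gene CTRB2 at 476 CPM, and cluster 19 (18 cells) ALB, the serum albumin gene. NPY reached 5849 CPM in the 47 epicardial-like cells, and TAC1 reached 112 CPM in cluster 2.

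HOXA and HOXB genes of groups 1 to 5, the 8 with at least 50 UMIs, were higher in VIP cluster 11 than in noradrenergic cluster 1 of hSGO, while the 4 measured HOXC and HOXD genes of these groups were within 2-fold. The 8 are thus the members that passed 2-fold, and the limit to HOXA and HOXB was set after these folds were seen. With HOX and signalling genes left out of the variable genes, the median log2 fold of the 8 was 3.18 (1.49 to 6.396), which argues against clusters drawn by the HOX genes themselves. Glial markers stood at a median of 4.82% of their cluster 0 level where at least 76.4% would be needed. This argues against glial cells mixed into cluster 11. At 2000 UMIs, 80.6% of cluster 11 against 12.9% of cluster 1 cells had a UMI of a member. Levels in CPM are already scaled by depth, and median UMIs were 18564 and 15085, so this share could hardly test depth as a cause. The same share was 58.4% in cluster 8, 51.2% in glial cluster 0 and 12.3% in sympathoadrenal-like cluster 10, so a high share was not particular to cluster 11. No biological explanation was tested, so a difference between these clusters in position along the body axis or in maturity stays open.

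Heart muscle transcripts appeared in non-cardiac clusters of hHFO. The highest mean of TNNT2 UMIs per cell was 17.9 times the lowest (12.7 in cluster 19 and 0.712 in cluster 15), which argues against free RNA alone as the whole cause. For own expression by the non-cardiac cells, the ratio of MYL7 to TNNT2 was compared with the cardiomyocyte-like ratio of 1.41. In 0 of 15 clusters was it 2-fold off (range 1.13 to 2.03). This argues against own expression at another ratio as the main source of these sums. It cannot decide on own expression at the same ratio, or at a low level beside transcripts from cardiomyocytes. In cluster 4 the mean of TNNT2 was 6.01 times the median, and 9.62% of cells had over 20 UMIs, which is consistent with remaining doublets with cardiomyocytes in part of its cells. The mean was 2.02 to 6.88 times the median in clusters 2, 6, 12, 13, 16, 17, 18 and 19 as well. In clusters 5, 8 and 9 it was 1.44, 1.16 and 1.21 times the median, and 0.691%, 0.590% and 0.692% of cells had over 20 UMIs, which argues against doublets as the main source there. The median was 0 in clusters 7, 11 and 15, which leaves no ratio, and the source in these and in clusters 5, 8 and 9 stays open. The design gives no group that would test a biological explanation other than own expression.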
